A study of Mus musculus with 16 samples.

How the data were processed

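RNA was sequenced from 16 mouse samples in 4 groups of 4, crossing an agent (IL-23 or vehicle) with the route by which a drug vehicle holding 0 mpk of compound had been dosed (per os, called oral here, or intraperitoneal). The labels name neither the tissue nor the day of harvest. Explanations below that weigh shares of epidermis or other tissues rest on the genes measured, not on a labelled tissue. The number that opens each title is used as the replicate name. No number is shared by any pair of samples, so nothing was paired, and the p-values measure the spread between these samples.

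Libraries were made with the TruSeq Stranded Total RNA kit and sequenced on a HiSeq 2500, per the labels' protocols. FastQC, STAR, featureCounts from Subread 1.5.0 and genome build GRCm38 are named in the submitters' processing notes. The annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here. The deposited values are raw read counts per gene, with no scaling by the authors that the values show: they are whole numbers whose sums differ between libraries. Totals ran from 6381990 to 14432930 counts per library. The table pairs gene IDs with symbols for 26357 genes, of which 5558 had no count in any library. Of these IDs, 25275 were matched in the RefSeq annotation of GRCm38.p6, 25172 of them with the same symbol or a synonym, and positions are given from it.

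Counts were tested in R 4.3.3 with edgeR 4.0.16: TMM scaling factors, filterByExpr on the 4 groups with its default minimum count of 10, which kept 14671 genes, and a quasi-likelihood fit of the 4 group means with 12 residual degrees of freedom. The contrasts were the IL-23 effect in oral mice, in intraperitoneal mice and as the mean over both routes, the difference of the IL-23 effect between routes (intraperitoneal minus oral), and the route effect (intraperitoneal minus oral) in vehicle mice and in IL-23 mice. Tests were 2-sided, with Benjamini-Hochberg adjustment over all genes tested, and a gene was called below an adjusted p of 0.05. Fitted log2 fold changes are given with a standard error (SE). For edgeR it was derived as the absolute log2 fold change over the square root of the quasi-likelihood F statistic, and for DESeq2 it is that tool's own. Levels are CPM, library-size-scaled counts with TMM factors, given as mean ± SD with n. Where a group held no count of a gene, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts, the ratio is given with a 95% exact binomial interval. Intervals and floors pool the counts of all libraries on a side, so they cover counting error only and leave out the spread between samples. The reads also carry no molecular identifiers.

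Gene lists, the rule for named genes, the tests and the alternatives other than those named below as added were chosen before the data were examined. There were 27 lists holding 494 gene names, of which 478 were found in the table. None of the mitochondrial genome list was found, which left 26 lists. The lists were IL-23/IL-17 axis, IL-1 and IL-36 family, antimicrobial and alarmin, activated keratinocyte, epidermal differentiation, neutrophil chemokine, neutrophil marker, monocyte and macrophage, dendritic and Langerhans cell, T cell, mast cell, type 2 and eosinophil, interferon response, STAT3 and NF-kB feedback, proliferation, sebaceous and lipid synthesis, adipocyte, skeletal muscle, cartilage, hair follicle, fibroblast and matrix, endothelium, red blood cell, Schwann cell and melanocyte, circadian clock and glucocorticoid response. Few genes, among them Csf2, Lcn2 and Per1, stand in more than 1 list. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with camera using a correlation estimated per list, and with fry, each adjusted over the 26 lists. Camera compares a list with all other genes, whereas fry asks whether a list's own genes move 1 way on balance. Named genes are a fixed set of 28, the 5 largest rises and 5 largest falls per contrast among called genes with a mean of at least 1 CPM in the higher group and no overlap between groups, and up to 4 members per list with the largest change past the threshold (the 2 most abundant where none passed). Members past the threshold against the rest of their list, and genes called in opposite directions in the routes, were named after their values were seen. Reads of near-identical families (Sprr2, Serpinb3, Saa, Lce, Mrgprb and Defb) may be shared between members, so their single-gene values are uncertain.

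Alternatives were RLE factors, upper-quartile factors, no count filter (20799 genes), a filter of 1 CPM in at least 4 libraries, DESeq2 1.42.0, limma-voom, only the groups compared, the mean log2 CPM of the skeletal muscle list as a covariate, no route term, and leaving out each library in turn. Plain library size without scaling factors, DESeq2 without the IL-23 intraperitoneal library 28, and the fit with no filter without that library were added after seeing the data. The pipeline was tested on simulated data with 200 genes changed and a planted list of 25 further genes raised 1.5-fold, all counted as true changes. Each contrast was drawn once, with far fewer genes changed than were called for the real IL-23 effect. For the IL-23 effect over both routes edgeR called 76% of genes planted at 1.5-fold and 84% of those planted at 2-fold, with 5 false calls among 206. For the difference between routes these shares were 22% and 66%, with 6 false calls among 146. DESeq2 gave more false calls, each time above the 5% intended: 22 among 208 for the IL-23 effect in oral mice, 13 among 219 over both routes, 20 among 171 for the difference and 17 among 199 for the route effect in vehicle mice (edgeR 5 among 183 and 3 among 178 for the first and last). The planted list of 25 genes at 1.5-fold was found by camera, by camera with an estimated correlation and by fry. The simulated genes were drawn independently of each other. This therefore does not show how camera with an estimated correlation performs on lists whose genes move together. Pairs of libraries within a group differed by far more than counting error, with a lowest chi-square per degree of freedom of 5.22 over 24 pairs, so no pair repeats the counts of 1 library.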

Results

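The libraries measured total RNA of mice given IL-23, the cytokine that maintains IL-17-producing T cells, or vehicle, in a study whose title concerns psoriasiform dermatitis driven by IL-23 and its use in drug discovery. Each agent was combined with an oral or an intraperitoneal drug vehicle, with n = 4 libraries per group. Total counts lay between 6381990 and 10078531 in the 8 IL-23 libraries and between 7159325 and 14432930 in the 8 vehicle libraries, and 17012 to 18287 genes were detected per library. The first principal component of log2 CPM held 71.2% of the variance and separated the agents without overlap, with IL-23 libraries at -71.5 to -47.2 and vehicle libraries at 43.6 to 67.0. On the second component, with 7.41% of the variance, IL-23 intraperitoneal library 28 stood at -62.5, and the other 15 libraries lay between -14.1 and 20.9. In library 28 the mean log2 CPM of the interferon response list was 5.59, against 2.93 to 3.67 in the 7 other IL-23 libraries. Its T cell list stood at 3.28 against 0.98 to 1.81, and its epidermal differentiation list at 7.32 against 8.08 to 9.15.

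**Figure D1:**
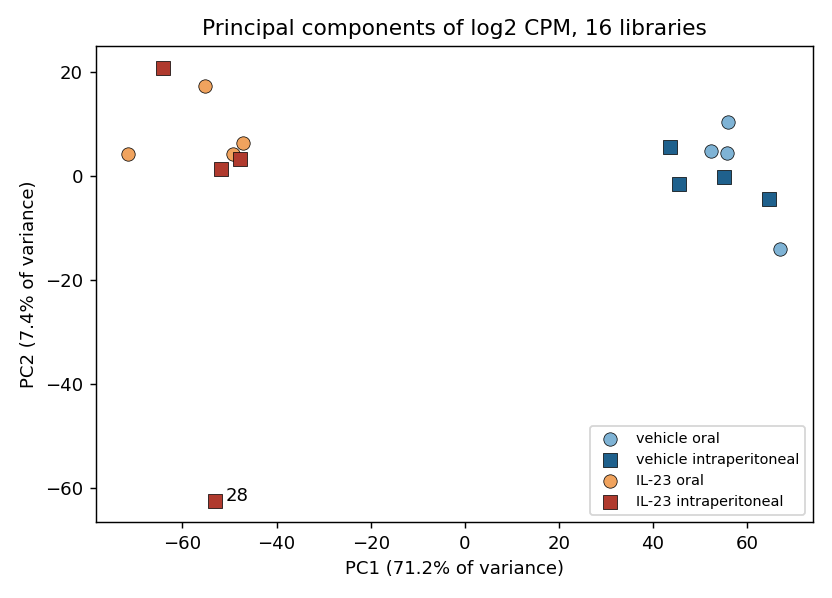
Each point is a library placed by the first component (x axis, 71.2% of the variance) and the second component (y axis, 7.41% of the variance) of log2 CPM, with colour and shape for the 4 groups. IL-23 libraries lie at -71.5 to -47.2 and vehicle libraries at 43.6 to 67.0 on the x axis, and library 28 lies at -62.5 on the y axis.

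The IL-23 effect over both routes asks how the agent changed gene levels whatever the dosing route, with 8 IL-23 against 8 vehicle libraries. The calprotectin subunit genes S100a8 and S100a9, whose protein is released by neutrophils and inflamed keratinocytes, rose from low to high levels. S100a8 (ID 20201, chromosome 3, 90669071 to 90670034) went from 27.1 ± 12.7 to 10280.0 ± 1655 CPM (SD, n = 8 each), a log2 fold change of 8.59 ± 0.30 (adjusted p = 9.91e-13). S100a9 (ID 20202, chromosome 3, 90692630 to 90695721) went from 38.9 ± 18.3 to 13380.0 ± 1988 CPM, a log2 fold change of 8.46 ± 0.30. Krt16 (ID 16666, chromosome 11, 100246091 to 100248902), a keratin of hyperproliferative epidermis, went from 132 ± 83.6 to 5547 ± 1559 CPM, a log2 fold change of 5.42 ± 0.47 (adjusted p = 1.98e-08). In total 10792 of 14671 genes (73.6%) were called, 5117 higher and 5675 lower, and 1141 and 1837 of these changed by at least 2-fold. DESeq2 called 11265 genes and limma-voom 10772. Without library 28 the count was 11028.

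Direction was given relative to TMM scaling, under which 47.4% of the calls were higher. With plain library size, an alternative added after seeing the data, the median of all genes shifted by -0.21 in log2 and 31.9% of the calls were higher (3515 higher and 7516 lower). With the mean of the skeletal muscle list as a covariate, which itself differs between the agents, the median SE went from 0.097 to 0.287 and the count fell to 2682.

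Of the 28 genes fixed in advance, 21 passed the count filter, and 20 of these rose and 0 fell. The exception was the filaggrin gene Flg, a barrier protein of the cornified layer, with 225 ± 49.5 CPM in vehicle and 178 ± 120 CPM in IL-23 libraries (log2 fold change -0.32 ± 0.34, adjusted p = 0.391, n = 8 each). Its intraperitoneal change was called without IL-23 intraperitoneal library 25 (log2 fold change -1.08). Among the genes that rose were the signalling genes Stat3, from 239 ± 12.5 to 612 ± 62.7 CPM, and Socs3, a feedback inhibitor of STAT3, from 17.0 ± 4.06 to 74.4 ± 14.8 CPM. Tnf rose from 1.90 ± 0.40 to 11.1 ± 2.61 CPM, and Krt6a, another keratin of activated epidermis, from 177 ± 102 to 2153 ± 757 CPM. The epithelial chemokine Ccl20, which attracts CCR6-bearing cells, rose from 4.59 ± 3.72 to 52.9 ± 36.6 CPM.

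**Figure D2:**
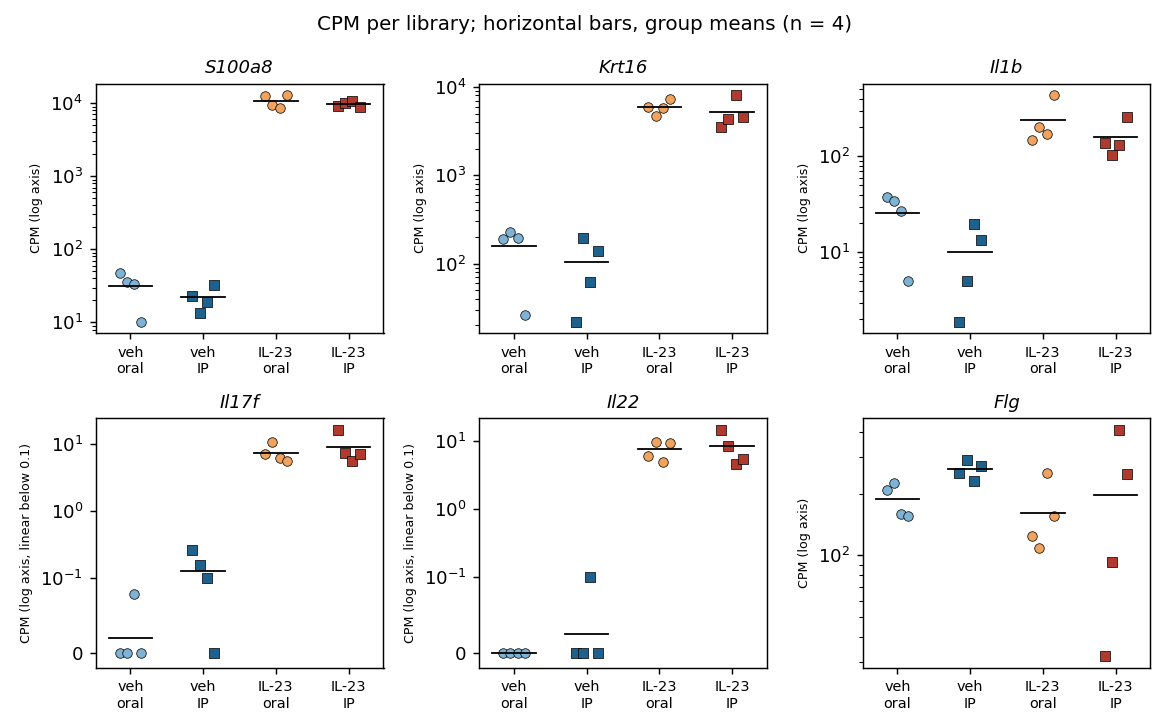
Each panel shows 1 gene, with CPM on the y axis (log scale, linear below 0.1 for Il17f and Il22) and the 4 groups on the x axis. Points are libraries and horizontal bars are group means. S100a8, Krt16, Il1b, Il17f and Il22 rose after IL-23 in the comparison over both routes, while Flg, at 225 and 178 CPM on average, did not pass the test.

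In the IL-23/IL-17 axis list, 12 of 16 tested members rose, 2 fell and 2 did not pass (the same counts when adjusted over the list alone). The cytokine genes Il17f and Il22 are products of type 17 lymphocytes. Il17f had 8 counts in vehicle and 523 in IL-23 libraries, with means of 0.075 ± 0.096 and 8.37 ± 3.74 CPM (log2 fold change 6.79 ± 0.41). Vehicle oral library 4 held the only count of its group, and without it the gene was at least 82.5-fold higher in oral mice. Il22 had 1 count in vehicle and 500 in IL-23 libraries, a ratio of 748 (95% interval 134 to 29580). Without vehicle intraperitoneal library 67, which held that count, it was at least 222-fold higher. The IL-10 family cytokine Il19 rose from 0.24 ± 0.31 to 70.9 ± 32.1 CPM and Il17c, an epithelial IL-17 cytokine, from 0.16 ± 0.13 to 3.30 ± 2.22 CPM. Il20rb, a receptor subunit for IL-19, IL-20 and IL-24, fell from 229 ± 14.7 to 186 ± 26.6 CPM. The median log2 fold change was 1.79, with an adjusted camera p of 0.000364 (adjusted p = 0.117 with an estimated correlation).

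Of the 28 fixed genes, 7 lay under the count filter and were tested in a fit of 20799 genes with no filter. Il17a, the signature cytokine of type 17 cells, had 0 counts in vehicle and 64 in IL-23 libraries, at least 31.9-fold higher (adjusted p = 0.000165). Library 28 held 37 of these counts, and without it the bound was 15.7-fold (adjusted p = 3.15e-05). The IL-23 receptor gene Il23r had 21 counts in vehicle and 68 in IL-23 libraries (adjusted p = 0.000739), 32 of them in library 28 (adjusted p = 0.00263 without it). Ifng, the type 1 cytokine, had 2 and 43 counts, a ratio of 32.1 (8.37 to 274), and 29 of the 43 lay in library 28. Its adjusted p was 0.00471. Without library 28 the ratio was 12.2 (2.80 to 111, adjusted p = 0.119), and without vehicle intraperitoneal library 67, which held both vehicle counts, it was at least 19.1-fold higher. Il12b, the subunit shared by IL-12 and IL-23, had 2 and 29 counts, a ratio of 21.7 (5.48 to 188). Its adjusted p was 6.57e-05. The ratio was 36.2 (6.01 to 1479) without vehicle oral library 33 and 39.8 (6.59 to 1624) without vehicle intraperitoneal library 50, which held 1 of the 2 counts each. The regulatory cytokine Il10 had 19 and 72 counts (adjusted p = 0.00154) and the neutrophil surface marker Ly6g 1 and 14 counts, a ratio of 20.9 (3.19 to 885, adjusted p = 0.0061). The call of Ly6g was lost without IL-23 oral library 26 (ratio 17.2, 2.44 to 745), and without vehicle intraperitoneal library 67, which held the vehicle count, it was at least 6.21-fold higher. The type 2 cytokine Il4 had 15 and 3 counts, a 3.34-fold lower level (0.946 to 18.0, adjusted p = 0.11), and was called without IL-23 oral library 14 (4.52-fold lower, 1.05 to 40.7) or without vehicle intraperitoneal library 59 (3.88-fold lower, 1.10 to 20.9).

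The lists of inflammatory mediators and their feedback genes were higher. In the IL-1 and IL-36 family 10 of 14 tested members rose, 1 fell and 3 did not pass, and the same held when adjusted over the list alone. Il1b rose from 18.0 ± 13.9 to 198 ± 107 CPM, and Il1f6, which encodes IL-36 alpha, from 12.9 ± 7.65 to 209 ± 61.3 CPM (n = 8 each). Il18, a cytokine of this family, fell from 44.6 ± 6.57 to 28.0 ± 6.58 CPM. The family's median log2 fold change was 1.28 (adjusted p = 0.0021, and adjusted p = 0.216 with an estimated correlation). In the antimicrobial and alarmin list 13 of 15 rose, 1 fell and 1 did not pass, also when adjusted over the list alone, with a median of 5.53 (adjusted p = 1.51e-07, and adjusted p = 0.117 with an estimated correlation). Lcn2, a siderophore-binding protein, rose from 4.6 ± 1.08 to 210 ± 45.0 CPM, and the lysozyme gene Lyz1 fell from 24.2 ± 10.8 to 8.26 ± 1.65 CPM. All 18 members of the STAT3 and NF-kB feedback list rose, also when adjusted over the list alone, with a median of 1.74 (adjusted p = 6.3e-08, and adjusted p = 0.157 with an estimated correlation). They included Nfkbiz, an inhibitor-family protein that mediates IL-17 responses, from 39.0 ± 5.67 to 175 ± 25.0 CPM, and the RNase gene Zc3h12a, from 25.8 ± 6.12 to 255 ± 40.1 CPM.

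Keratinocyte genes moved in both directions. All 27 tested members of the activated keratinocyte list rose, also when adjusted over the list alone, with a median of 5.19 (adjusted p = 8.33e-15, and adjusted p = 0.205 with an estimated correlation). The cornified envelope gene Sprr2d went from 10.3 ± 6.83 to 1278 ± 349 CPM and Serpinb3a from 4.36 ± 2.35 to 560 ± 126 CPM. In the epidermal differentiation list 15 of 24 rose, 2 fell and 7 did not pass, and 14 rose and 2 fell when adjusted over the list alone. The suprabasal keratin gene Krt1 rose from 918 ± 355 to 9957 ± 2397 CPM, and Casp14, a protease of cornification, from 46.5 ± 9.46 to 232 ± 73.1 CPM. Flg2, a filaggrin-related barrier gene, fell from 396 ± 81.7 to 11.8 ± 8.74 CPM (log2 fold change -5.07 ± 0.32, adjusted p = 5.67e-10), and the keratin gene Krt77 from 20.5 ± 6.79 to 9.03 ± 8.19 CPM. The differentiation median was 0.52 (adjusted p = 0.00994, and adjusted p = 0.587 with an estimated correlation). In the proliferation list 24 of 25 rose, 0 fell and 1 did not pass, and 25 rose when adjusted over the list alone. The mitotic genes Birc5 and Plk1 rose from 34.8 ± 4.24 to 93.5 ± 14.4 CPM and from 22.7 ± 3.81 to 57.7 ± 7.71 CPM. The proliferation median was 0.98 (adjusted p = 1.04e-08, and adjusted p = 0.263 with an estimated correlation).

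Genes of neutrophils and other myeloid cells also rose. All 7 tested neutrophil chemokine genes and all 9 tested neutrophil marker genes rose, also when adjusted over the list alone, with medians of 4.49 and 3.26. Their adjusted camera p-values were 0.000658 and 0.00097 (adjusted p = 0.117 and adjusted p = 0.263 with an estimated correlation). The chemokine Cxcl1 rose from 1.63 ± 0.63 to 42.8 ± 26.4 CPM, and its receptor gene Cxcr2 from 1.25 ± 0.78 to 22.5 ± 5.89 CPM. In the monocyte and macrophage list 18 of 21 rose, 0 fell and 3 did not pass (the same when adjusted over the list alone), with a median of 1.52 (adjusted p = 0.000263, and adjusted p = 0.263 with an estimated correlation). Library 28 had a mean of 5.90 for this list against 4.13 to 5.07 in the 7 other IL-23 libraries, and without it the median was 1.17 (adjusted p = 0.000173). Ccl7, a monocyte chemoattractant, rose from 5.45 ± 1.51 to 47.4 ± 25.3 CPM. In the dendritic and Langerhans cell list 13 of 15 rose, 1 fell and 1 did not pass (the same when adjusted over the list alone), with a median of 0.85 (adjusted p = 0.00134, and adjusted p = 0.216 with an estimated correlation). Ccl17, a chemokine of dendritic cells, rose from 1.06 ± 1.14 to 9.48 ± 4.18 CPM, and the homing receptor gene Ccr7 from 0.59 ± 0.31 to 2.70 ± 1.07 CPM. The growth factor receptor gene Flt3 fell from 5.18 ± 0.99 to 3.27 ± 1.19 CPM.

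In the interferon response list 18 of 23 rose, 0 fell and 5 did not pass, also when adjusted over the list alone, with a median of 1.29 (adjusted p = 0.00182, and adjusted p = 0.544 with an estimated correlation). Library 28 stood at 5.59 for this list's mean log2 CPM, above the 7 other IL-23 libraries, and without it the median was 0.79 (adjusted p = 0.00149). The guanylate-binding protein gene Gbp2 had a log2 fold change of 2.61 ± 0.51, and of 1.64 without library 28. The chemokine gene Cxcl9 had 3.29 ± 0.67, and 2.04 without it. In the T cell list 9 of 15 rose, 0 fell and 6 did not pass, also when adjusted over the list alone. Icos, a costimulatory receptor, rose from 0.74 ± 0.28 to 4.70 ± 4.94 CPM and Cd2 from 0.74 ± 0.38 to 2.06 ± 1.33 CPM. The list's median of 0.64 did not pass camera (adjusted p = 0.0737, and adjusted p = 0.582 with an estimated correlation), though fry called it (adjusted p = 0.0251). Library 28 stood at 3.28 for the mean of this list, against 0.98 to 1.81, and without it the median was 0.54 (adjusted p = 0.109) and the log2 fold change of Icos 1.99 instead of 2.50. Camera called the list with plain library size (median 0.45), without IL-23 oral library 14 (median 0.80), without IL-23 intraperitoneal library 31 (0.77) or without IL-23 intraperitoneal library 61 (0.81). In the type 2 and eosinophil list 6 of 9 rose, 1 fell and 2 did not pass, also when adjusted over the list alone, with a median of 1.81. The receptor gene Il4ra rose from 33.7 ± 5.13 to 138 ± 40.7 CPM and the chemokine gene Ccl8 from 13.1 ± 5.19 to 109 ± 74.9 CPM, whereas the epithelial cytokine gene Tslp fell from 5.03 ± 0.93 to 3.25 ± 0.91 CPM. The adjusted camera p was 0.0465 (adjusted p = 0.263 with an estimated correlation), and it was 0.0609 without library 28 and 0.055 with RLE factors.

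Mast cell genes were lower. In that list 9 of 10 fell, 1 rose and 0 did not pass, also when adjusted over the list alone, with a median of -1.30 (adjusted p = 0.00671, and adjusted p = 0.263 with an estimated correlation). This median lay between those of the skeletal muscle and cartilage lists below, so a fall of this size was not particular to mast cell genes. The mast cell protease gene Cpa3 fell from 25.4 ± 8.80 to 8.03 ± 4.41 CPM and the receptor gene Mrgprb2 from 5.10 ± 1.37 to 0.37 ± 0.25 CPM. The member that rose, Hdc, encodes histidine decarboxylase, which other myeloid cells can also express, and went from 10.1 ± 4.93 to 64.5 ± 40.7 CPM. A related receptor gene, Mrgprb3, was among the largest falls, with 150 counts in vehicle and 2 in IL-23 libraries, a ratio of 50.2 (13.7 to 418).

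Genes of muscle, fat, cartilage, nerve and pigment cells were lower together. All 25 skeletal muscle genes fell, with a median of -1.22 (adjusted p = 8.96e-08, and adjusted p = 0.263 with an estimated correlation). All 15 adipocyte genes fell, with a median of -1.64 (adjusted p = 1.26e-05, and adjusted p = 0.216 with an estimated correlation). All 13 genes of the Schwann cell and melanocyte list fell, with a median of -1.73 (adjusted p = 7.06e-06, and adjusted p = 0.205 with an estimated correlation). In the cartilage list 13 of 14 fell, 0 rose and 1 did not pass, with a median of -1.35 (adjusted p = 0.000341, and adjusted p = 0.263 with an estimated correlation). These 4 counts were the same when adjusted over the list alone. The myosin gene Myh2 fell from 185 ± 50.5 to 44.4 ± 9.11 CPM, the lipid droplet gene Plin1 from 39.0 ± 8.43 to 8.10 ± 3.25 CPM and the collagen gene Col9a1 from 43.9 ± 11.8 to 13.8 ± 2.93 CPM.

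In the sebaceous and lipid synthesis list 16 of 25 fell, 3 rose and 6 did not pass, also when adjusted over the list alone, with a median of -0.69 (adjusted p = 0.00524, and adjusted p = 0.399 with an estimated correlation). The desaturase gene Scd1 fell from 18510.0 ± 2365 to 7079 ± 1092 CPM and the elongase gene Elovl6 from 3270.0 ± 540.0 to 975 ± 210.4 CPM. In the hair follicle list 8 of 12 fell, 1 rose and 3 did not pass, also when adjusted over the list alone. The stem cell marker gene Lgr5 fell from 15.9 ± 2.73 to 6.48 ± 1.27 CPM, and the homeobox gene Msx2 from 27.1 ± 2.40 to 9.21 ± 2.43 CPM. Tchh, which encodes a protein of the inner root sheath, rose from 10.2 ± 1.32 to 16.3 ± 2.92 CPM. The follicle median of -0.73 had an adjusted camera p of 0.05003 (adjusted p = 0.45 with an estimated correlation), just over the threshold. It was called by fry (adjusted p = 8.91e-05), with RLE factors, and when any library other than IL-23 oral 14 or 24, vehicle oral 33 or 51 or vehicle intraperitoneal 49 was left out (medians -1.07 to -0.70, and -0.98 without library 28).

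In the fibroblast and matrix list 16 of 24 fell, 5 rose and 3 did not pass, also when adjusted over the list alone. The matrix gene Sparc fell from 542 ± 101 to 216 ± 39.5 CPM, whereas Timp1, an inhibitor of matrix proteases, rose from 12.3 ± 2.82 to 60.7 ± 24.0 CPM. The matrix median of -0.62 did not pass camera (adjusted p = 0.119, and adjusted p = 0.694 with an estimated correlation), but did by fry (adjusted p = 0.0459). Library 28 had a mean of 7.83 for this list against 6.49 to 6.88 in the 7 other IL-23 libraries, and without it the median was -0.89 (adjusted p = 0.00821). In the endothelium list 7 of 18 fell, 4 rose and 7 did not pass, and 6 fell and 4 rose when adjusted over the list alone. The adhesion molecule gene Icam1 rose from 24.3 ± 4.20 to 61.7 ± 18.9 CPM and the lymphatic regulator gene Prox1 fell from 1.80 ± 0.79 to 0.59 ± 0.44 CPM. Its median was -0.29 (adjusted p = 0.455, adjusted p = 0.808 with an estimated correlation and adjusted p = 0.236 by fry). In the red blood cell list 2 of 3 fell, 0 rose and 1 did not pass, also when adjusted over the list alone, with a median of -0.84 (adjusted p = 0.455, and adjusted p = 0.569 with an estimated correlation), and fry called it (adjusted p = 0.00302). The haem synthesis gene Alas2 fell from 3.88 ± 0.65 to 2.19 ± 0.69 CPM.

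In the circadian clock list 14 of 16 fell, 0 rose and 2 did not pass, also when adjusted over the list alone, with a median of -0.91 (adjusted p = 0.00116, and adjusted p = 0.205 with an estimated correlation). The clock output genes Dbp and Hlf fell from 38.0 ± 9.49 to 14.4 ± 4.78 CPM and from 232 ± 12.9 to 74.6 ± 12.5 CPM. In the glucocorticoid response list 8 of 15 fell, 6 rose and 1 did not pass, and 8 fell and 7 rose when adjusted over the list alone. The transcription factor genes Zbtb16 and Klf9 fell from 16.6 ± 3.69 to 4.68 ± 0.67 CPM and from 70.6 ± 8.15 to 22.7 ± 5.90 CPM. Its median was -0.62 and its mean -0.03, and it did not pass camera (adjusted p = 0.663, and adjusted p = 0.796 with an estimated correlation) or fry (adjusted p = 0.264). Over the 26 lists, camera with the preset correlation called 20, camera with an estimated correlation 0, and fry 24.

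**Figure D3:**
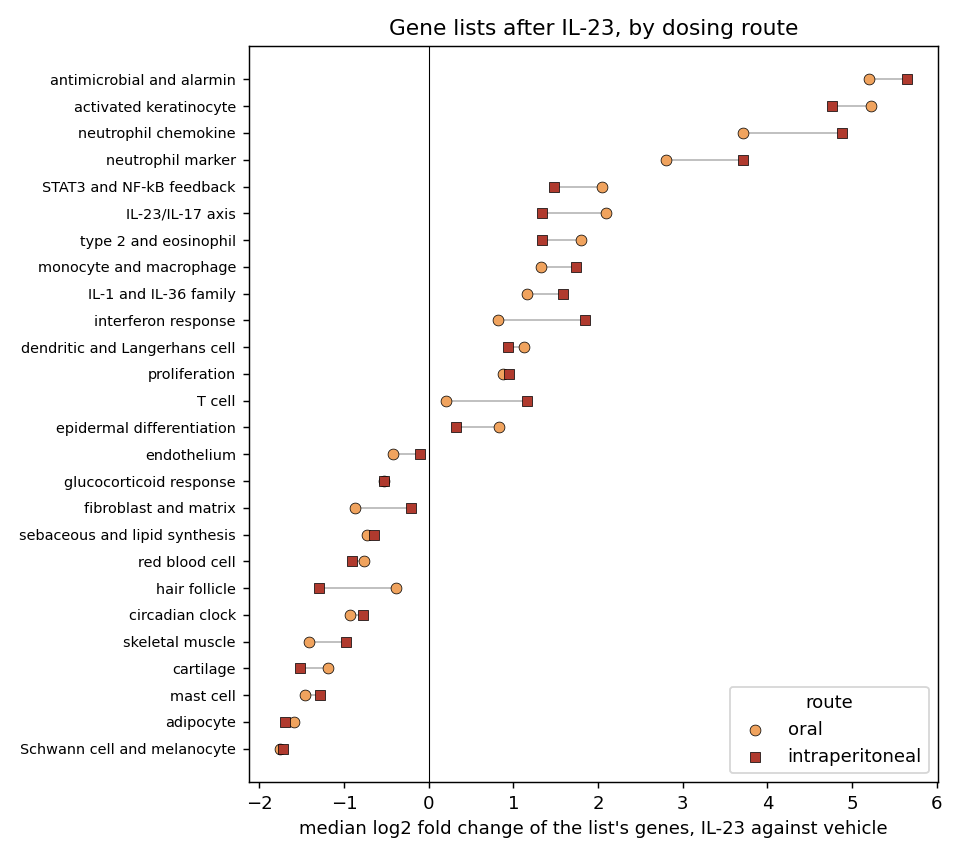
Gene lists are ordered on the y axis by their change, with the lowest at the bottom. For each list, joined points show the median log2 fold change after IL-23 (x axis), a circle for oral and a square for intraperitoneal mice. Activated keratinocyte and antimicrobial lists lie at the upper right and muscle, adipocyte, cartilage and Schwann cell and melanocyte lists at the lower left.

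The largest changes over both routes, by the rule for named genes, were rises of Slc26a4, Sprr2b, Uox, S100a8 and Il22 and falls of Mrgprb3, Flg2, Tgm7, Scgb1b27 and Krtap3-2. Slc26a4 (ID 23985, chromosome 12, 31519814 to 31560055), which encodes the anion exchanger pendrin, had 1 count in vehicle and 966 in IL-23 libraries, a ratio of 1444 (259 to 57100). Without vehicle intraperitoneal library 50, which held that count, it was at least 441-fold higher. Uox (ID 22262, chromosome 3, 146597149 to 146631483), which encodes urate oxidase, rose from 0.26 ± 0.22 to 150.4 ± 40.9 CPM (log2 fold change 8.88 ± 0.27). Sprr2b rose from 0.67 ± 0.52 to 393 ± 100.3 CPM. The hair keratin-associated gene Krtap3-2 fell from 10.7 ± 3.99 to 0.38 ± 0.29 CPM and the secretoglobin gene Scgb1b27 from 4.28 ± 2.28 to 0.16 ± 0.25 CPM (log2 fold change -4.78, with no count left in IL-23 oral mice without library 68). The transglutaminase gene Tgm7 fell from 4.02 ± 1.5 to 0.12 ± 0.20 CPM (log2 fold change -4.94, and 3 IL-23 counts without IL-23 intraperitoneal library 31, 70.7-fold lower, 24.0 to 345).

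In oral mice the IL-23 effect, from 4 against 4 libraries, had S100a8 at 32.0 ± 15.8 CPM in vehicle and 10880.0 ± 2216 CPM in IL-23 mice, a log2 fold change of 8.41 ± 0.42. Krt16 rose from 160.0 ± 90.7 to 5960.0 ± 1051 CPM and Krt6a from 238 ± 115 to 2512 ± 881 CPM. The largest rises were of Slc26a4 (0 and 563 counts, at least 271-fold higher), Sprr2b (log2 fold change 9.83 ± 0.41), Sprr2j-ps, Il19 and Il22 (0 and 239 counts, at least 115-fold higher). Sprr2j-ps had 2 and 1604 counts, a ratio of 1156 (320 to 9557). The largest falls were of Mrgprb3 (80 and 0 counts, at least 18.5-fold lower), Tgm7 (226 and 2 counts, a ratio of 78.4, 21.4 to 651), Scgb1b27, Flg2 and Krtap3-2. Without vehicle oral library 33, Il19 had 2 vehicle counts, a ratio of 1201 (332 to 9922), and Sprr2j-ps had 0, at least 518-fold higher. Without IL-23 oral library 68, Scgb1b27 went from 3 IL-23 counts (38.8-fold lower, 13.1 to 190) to 0 (at least 27.3-fold lower), the log2 fold change of Flg2 from -4.96 to -5.57 and that of Krtap3-2 from -4.57 to -5.24. Of the 21 fixed genes tested, 20 rose and 0 fell, though the call of Csf2, a myeloid growth factor, was lost without IL-23 oral library 24 (log2 fold change 3.07, and 2.29 without it). In total 9280 genes were called, 4288 higher (46.2%) and 4992 lower, and 1135 and 1924 of these changed by at least 2-fold. DESeq2 called 9368, limma-voom 9282 and the fit without library 28 called 9768. Plain library size shifted the median by -0.20 and gave 31.0% higher (2942 higher and 6553 lower). With the muscle covariate the count was 1693.

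In intraperitoneal mice S100a8 rose from 22.3 ± 8.17 to 9688 ± 734 CPM (n = 4 each), a log2 fold change of 8.78 ± 0.43. Krt16 rose from 105 ± 77.8 to 5134 ± 2028 CPM and Krt6a from 117 ± 33.4 to 1795 ± 468 CPM. The largest rises were of Sprr2b (log2 fold change 8.81 ± 0.38), S100a8, Uox, S100a9 and Slc26a4 (1 and 403 counts, a ratio of 626, 112 to 24770). The largest falls were of Flg2, Krtap3-2 (log2 fold change -4.94 ± 0.57), Car6 (-4.54 ± 0.56), a secreted carbonic anhydrase, Scgb1b27 and Mrgprb3 (70 and 2 counts, a ratio of 22.5, 6.01 to 190). Leaving out vehicle library 49 moved Uox from 8.74 to 9.42, and without vehicle library 50 Slc26a4 had no vehicle count and was at least 174-fold higher. Leaving out IL-23 library 25 moved Flg2 from -5.18 to -5.89 and left Scgb1b27 with 2 IL-23 counts, 58.0-fold lower (15.9 to 482). Of the 21 fixed genes tested, 20 rose and 0 fell. In total 9056 genes were called, 4519 higher (49.9%) and 4537 lower, and 1131 and 1697 of these changed by at least 2-fold. DESeq2 called 9169, limma-voom 8972 and the fit without library 28 called 9037. Plain library size shifted the median by -0.22 and gave 31.5% higher (2871 higher and 6248 lower), and upper-quartile factors shifted it by -0.10. With the muscle covariate the count was 2938.

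The routes share no library, so the IL-23 effects can be set side by side. The same 3794 genes were higher in both routes, where independent calls would give 1321, and 4024 were lower in both, where they would give 1544. The 2 genes called in opposite directions, named after their values were seen, were the hair keratin-associated gene Krtap26-1, with a log2 fold change of 2.66 ± 0.77 in oral mice and a 9.45-fold lower level (3.03 to 47.6, with 3 IL-23 counts) in intraperitoneal mice, and the actin-binding gene Palld, with -0.42 ± 0.16 and 0.41 ± 0.16. For Krtap26-1 the oral value was 3.32 without vehicle oral library 33, the intraperitoneal level was 20.2-fold lower (3.44 to 816, with 1 IL-23 count) without IL-23 intraperitoneal library 31, and the test of the difference gave an adjusted p of 0.875. The oral call of Palld was lost without IL-23 library 14 (-0.42) or 26 (-0.29) or vehicle library 27 (-0.30) or 51 (-0.40). Its intraperitoneal call was lost without IL-23 library 28 (0.34) or 61 (0.42) or vehicle library 49 (0.36), 67 (0.42) or 50 (0.37). Across 14671 genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.929 and a Spearman rho of 0.928, with a covariance of 0.907, and 89.8% had the same sign.

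The difference of the IL-23 effect between routes asks whether the route of the drug vehicle altered the response. None of the 21 fixed genes tested passed, and 1 of them had an unadjusted p below 0.05, the beta-defensin gene Defb4 (log2 difference 2.38 ± 0.99, adjusted p = 0.875, and a fitted 3.68 without vehicle intraperitoneal library 67, where 1 count of that group remained). The suprabasal keratins Krt10 and Krt2 had differences of 0.04 ± 0.28 and 0.01 ± 0.29 in log2, which turn negative under upper-quartile and plain library-size scaling. In all, edgeR called 0 genes, 796 had an unadjusted p below 0.05, and the smallest adjusted p was 0.595. limma-voom called 0. DESeq2 called 1, Rbm4, an RNA-binding protein gene named here after its values were seen (log2 difference -0.69 ± 0.14, adjusted p = 0.0363), and 0 without library 28. For lists, camera with the preset correlation called 9, of which the interferon response list had the largest median difference, 0.94 (adjusted p = 0.0414). It was -0.21 without library 28 (adjusted p = 0.313), and the call was also lost without IL-23 oral library 14 (0.86), 24 (0.81) or 68 (0.88), vehicle oral library 51 (0.86) or vehicle intraperitoneal library 49 (0.78) or 59 (0.83). Without library 28 the epidermal differentiation list went from -0.41 (adjusted p = 3.54e-07) to -0.16 (adjusted p = 0.00493), and without IL-23 intraperitoneal library 25 to -0.90 (adjusted p = 5.71e-16). None of the 9 was called with an estimated correlation (lowest adjusted p = 0.674) or by fry (lowest adjusted p = 0.675).

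The route effect in vehicle mice compares intraperitoneal with oral dosing without IL-23, 4 against 4 libraries. The fast myosin gene Myh1 was at 1267 ± 336 CPM in oral and 821 ± 163 CPM in intraperitoneal mice (log2 fold change -0.63 ± 0.21, adjusted p = 0.598), and the calcium pump gene Atp2a1 at 1111 ± 255 and 759.5 ± 65.0 CPM (adjusted p = 0.598). The skeletal muscle list had a median of -0.58, and 23 of its 25 members fell when adjusted over the list alone, 0 over all genes. Camera gave it an adjusted p of 1.65e-21 (adjusted p = 0.267 with an estimated correlation), and fry 0.239. The epidermal differentiation list had a median of 0.46 (adjusted p = 3.23e-09, and adjusted p = 0.532 with an estimated correlation). Of 26 lists, camera with the preset correlation called 11, and 0 were called with an estimated correlation (lowest adjusted p = 0.267) or by fry (lowest adjusted p = 0.239). These 2 lists, IL-1 and IL-36 family (median 0.29), dendritic and Langerhans cell (0.26) and type 2 and eosinophil (0.55) were called whichever library was left out. The other 6 were neutrophil chemokine (-1.05), IL-23/IL-17 axis (0.28, and 0.18 with low-count members at their bound), activated keratinocyte (0.26), STAT3 and NF-kB feedback (0.11), sebaceous and lipid synthesis (-0.16) and adipocyte (-0.21). Without vehicle intraperitoneal library 49 the calls of neutrophil chemokine (-0.74), sebaceous (-0.096) and adipocyte (-0.094) were lost, and without 59 those of the IL-23/IL-17 axis (0.10), activated keratinocyte (0.035), STAT3 and NF-kB (0.045) and sebaceous (-0.11) lists. Without vehicle intraperitoneal library 50 those of activated keratinocyte (0.34) and STAT3 and NF-kB (0.034) were lost, and without vehicle oral library 51 those of the IL-23/IL-17 axis (0.18) and activated keratinocyte (0.17). The sebaceous call was also lost without vehicle oral library 33 (-0.088) or 4 (-0.13), and without IL-23 oral library 14, 24 or 68 or IL-23 intraperitoneal library 25 (-0.16 each). edgeR called 0 genes, 1087 had an unadjusted p below 0.05, and the smallest adjusted p was 0.598. limma-voom called 0. DESeq2 called 1, Cdk8, a kinase gene of the Mediator complex named here after its values were seen (log2 fold change 0.49 ± 0.10, adjusted p = 0.0131). Without library 28, a library of neither group, DESeq2 called 78.

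The route effect in IL-23 mice compares intraperitoneal with oral dosing under IL-23. The vascular gene Plvap was at 48.4 ± 9.49 CPM in oral and 74.3 ± 19.0 CPM in intraperitoneal mice (n = 4 each, adjusted p = 0.265). The gamma delta T cell gene Cd163l1 was at 5.25 ± 1.14 and 12.6 ± 13.9 CPM (adjusted p = 0.332), a log2 fold change of 1.27, and of 0.08 without library 28. The T cell list had a median of 0.83 (adjusted p = 0.000417, and adjusted p = 0.965 with an estimated correlation), and without library 28 the median was 0.27 (adjusted p = 0.0842). The endothelium list had 0.44 (adjusted p = 0.000417, and adjusted p = 0.965 with an estimated correlation), and 0.22 without library 28 (adjusted p = 0.0842). The hair follicle list had -0.75 (adjusted p = 0.000417, and adjusted p = 0.965 with an estimated correlation). It ran from -1.24 (without IL-23 oral library 14) to -0.50 (without IL-23 oral library 68) when 1 library was left out, and was called each time. Of 26 lists, camera with the preset correlation called 8, and 0 were called with an estimated correlation or by fry (lowest adjusted p = 0.826). The other 5 were interferon response (median 0.79, and -0.20 without library 28), fibroblast and matrix (0.48, and 0.0041 without it), activated keratinocyte (-0.27, and -0.11), cartilage (-0.32, and -0.22) and skeletal muscle (-0.26, and -0.25). Without library 28 only hair follicle and skeletal muscle of the 8 were called. The skeletal muscle call was lost without IL-23 oral library 68 (-0.074), and that of cartilage without IL-23 oral library 14 (-0.20) or 68 (-0.15) or IL-23 intraperitoneal library 61 (-0.27). That of activated keratinocyte was lost without IL-23 oral library 26 (-0.10) or IL-23 intraperitoneal library 31 (-0.21) or 61 (-0.26), and with RLE factors (-0.27). edgeR called 0 genes, 1874 had an unadjusted p below 0.05, the smallest adjusted p was 0.0841, and limma-voom called 0. DESeq2 called 57, 45 higher and 12 lower, and 57 without library 28, of which 26 were the same genes.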

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

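Of the tests below, the other splits of the samples and the differences between routes were planned, whereas the tests on library 28 were chosen only after the result was seen.

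For the IL-23 effect in oral mice, 1 of 35 splits of the 8 libraries, the real split, gave as many calls as its 9280, and the highest of the others gave 0. In intraperitoneal mice it was also 1 of 35, with 9056 calls against 211. Over both routes it was 1 of 100 drawn splits, with 10792 calls against 7756 in a split that exchanged 1 pair of libraries. In each case the real split gave the most calls, at the lowest share these numbers of splits allow (2.86%, 2.86% and 1%). Chance is therefore argued against for these 3 counts but not excluded. The other 3 counts are 0, which any split reaches, so the splits say nothing about chance there: 100 of 100 for the difference between routes (highest of the others 0), 35 of 35 for the route effect in vehicle mice (highest 1) and 35 of 35 in IL-23 mice (highest 2).

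IL-23 intraperitoneal library 28 stood apart from the 7 other IL-23 libraries on the second component, with higher interferon, T cell, fibroblast and endothelium list means and with lower ones for activated keratinocyte (7.78 against 8.24 to 8.95) and epidermal differentiation (7.32 against 8.08 to 9.15). A vehicle library under a wrong label is argued against, since its activated keratinocyte mean exceeded that of every vehicle library by at least 3.50 in log2, and so is sequencing depth, since its total of 8818074 counts and its 17495 detected genes lay within the range of those 7. A lower share of epidermis could give the lower keratinocyte means, but as the whole cause it would raise the lists of all non-epidermal tissues alike, and 3 of 6 were above the range of the others. These were fibroblast and matrix (7.83 against at most 6.88), endothelium (4.48 against at most 3.73) and, by the last digit, Schwann cell and melanocyte, while muscle, cartilage and adipocyte lay within it. What stays open, untested, is a different mix of immune, stromal and epidermal cells or a different response in that animal, whose activated keratinocyte mean was the lowest of the 8.

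A sample far from the rest of its group, by the gap to its nearest neighbour over the group's range (Dixon's test at its 95% limit for 4 samples), was seen in 18 of 208 groups, and 2 of the 18 were library 28. Chance gives about 1 in 20 groups, or 10.4, but in 4 of the 18 the other 3 samples had no count, which fixes the outcome. Library 28 stood out in its interferon response mean of 5.59 in log2 CPM and its Il17f level of 16.6 CPM. List means so marked were IL-1 and IL-36 family at 4.81 and skeletal muscle at 7.45 in vehicle intraperitoneal library 49, antimicrobial and alarmin at 6.64 in IL-23 intraperitoneal library 31, neutrophil marker at 4.21 in IL-23 oral library 26, and glucocorticoid response at 6.18 in vehicle intraperitoneal library 50 and 6.05 in IL-23 oral library 68. The 4 groups with no other count held, in CPM, Il17f at 0.0795 in vehicle oral library 4, Il22 at 0.1001 in vehicle intraperitoneal library 67, and Csf2 at 0.238 and Il6 at 0.0794 in vehicle intraperitoneal library 59. Other gene levels so marked were Csf2 at 2.66 in IL-23 oral library 24 and 6 in IL-23 intraperitoneal library 25, and Ccl20 at 96.6 in the latter. Vehicle intraperitoneal library 59 had Ccl20 at 13.7, and vehicle intraperitoneal library 50 had S100a9 at 49.1. IL-23 oral library 14 stood at 17.4 on the second component.

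The IL-23 effect differed between routes (intraperitoneal minus oral) for 9 lists by camera with the preset correlation, and for 0 with an estimated correlation (lowest adjusted p = 0.674) or by fry (lowest adjusted p = 0.675). The median differences were -0.55 for activated keratinocyte, -0.41 for epidermal differentiation, -0.27 for STAT3 and NF-kB feedback, -0.23 for cartilage and -0.63 for hair follicle. They were 0.94 for interferon response, 0.33 for skeletal muscle, 0.53 for fibroblast and matrix and 0.43 for endothelium. The activated keratinocyte median ran from -0.79 (without IL-23 intraperitoneal library 25) to -0.23 (without vehicle intraperitoneal library 59) when 1 library was left out. Of the 9 calls, those of epidermal differentiation and skeletal muscle held whichever library was left out. For both lists the routes lay further apart in vehicle than in IL-23 mice. The mean log2 CPM of skeletal muscle was 7.76 (oral) and 7.20 (intraperitoneal) in vehicle mice, and 6.33 and 6.11 in IL-23 mice. That of epidermal differentiation was 7.66 and 8.07 in vehicle mice, and 8.37 and 8.27 in IL-23 mice. Without library 28 the median was -0.21 for interferon response, 0.077 for fibroblast and matrix, 0.22 for endothelium and -0.19 for cartilage, and none of these 4 was called by camera. The call was also lost without vehicle oral library 51 for activated keratinocyte (-0.48), interferon response (0.86), fibroblast and matrix (0.37) and endothelium (0.18), and without vehicle oral library 33 for cartilage (-0.19). It was lost without IL-23 oral library 14 for interferon response (0.86), cartilage (-0.18) and fibroblast and matrix (0.47), without 24 for interferon response (0.81) and fibroblast and matrix (0.50), and without 26 for endothelium (0.37). Without IL-23 oral library 68 it was lost for interferon response (0.88), cartilage (-0.075), hair follicle (-0.31) and endothelium (0.37), and without IL-23 intraperitoneal library 61 for cartilage (-0.22). Without vehicle intraperitoneal library 49 it was lost for interferon response (0.78) and cartilage (-0.049), without 59 for interferon response (0.83), and without 50 for STAT3 and NF-kB feedback (-0.21) and fibroblast and matrix (0.41).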

How the results depend on the processing

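Of the alternatives here, plain library size and DESeq2 without library 28 were chosen only after the data were seen. Over 27 settings the called counts stayed within 1.5 times of the reported ones except as follows. With the skeletal muscle mean as a covariate they were 1693 (oral), 2938 (intraperitoneal) and 2682 (both routes), as that mean separates the agents and the median SE over both routes went from 0.097 to 0.287. DESeq2 called 1 gene for the difference between routes and 1 for the route effect in vehicle mice (78 without library 28), and 57 for the route effect in IL-23 mice (57 without library 28). The cause was not tested, though in simulated data 20 of 171 DESeq2 calls for the difference and 17 of 199 for the route effect in vehicle mice were false (edgeR 6 of 146 and 3 of 178). Leaving out 1 library gave 8457 to 9768 calls for oral, 8310 to 9092 for intraperitoneal and 10567 to 11028 for both routes. List tests over both routes gave 20 calls, 20 to 22 without 1 library, 0 with an estimated correlation and 24 by fry. The correlation between routes was 0.929, 0.901 to 0.932 without 1 library, and 0.9596 over the 10466 genes with a mean of at least 10 CPM. Of 5562 values of named genes under these settings, 5442 kept direction and side of the threshold, 87 lost the call (62 of them under the muscle covariate), 6 gained it and 27 turned. Of 1080 values of 54 list results (26 lists over both routes, and those called for the difference between routes or a route effect), 925 kept both, 132 lost the call (48 with an estimated correlation and 28 by fry), 21 gained it and 2 turned. These were the interferon response medians without library 28: that of the difference, 0.94, was -0.21 to 1.24 without 1 library, and that of the route effect in IL-23 mice, 0.79, was -0.20 to 1.05, as library 28 lies far above the others for this list. The muscle covariate turned Flg to 0.86 (oral), 0.41 (intraperitoneal) and 0.64 (both), Krt73 to 0.18, Sele to -0.45, Atp2a1 to -0.0296 for the difference and 0.11 for the route effect in vehicle mice, and Myh1 to 0.0491 there; the cause was not tested. The difference of Krt10, 0.04, turned to -0.000136 with upper-quartile factors, -0.0138 with plain library size and -0.0409 with limma-voom, and was -0.21 to 0.20 without 1 library. That of Krt2, 0.01, turned to -0.00144 with RLE factors, -0.0236 with upper-quartile factors, -0.0394 with plain library size, -0.00124 with DESeq2 and -0.0644 with limma-voom, and was -0.28 to 0.17 without 1 library. Both lie far below their SE of 0.28 and 0.29. Depth limits Il17a, Il23r, Il12b, Ifng, Il4, Il10 and Ly6g, which lay under the count filter.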

Other observations

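Of the tests below, those of the clock list and of the equal dilution of 4 tissues were planned before the result was seen, whereas the tests of scaling and of an equal dilution of 6 tissues for the muscle, fat, cartilage and nerve or pigment cell lists were chosen only after it. Plain library size, among the scalings used below for the clock list too, was added after seeing the data.

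Genes of pigment cells fell over both routes (n = 8 each). Tyrp1 and Dct, enzymes of melanin synthesis, went from 12.3 ± 3.84 to 2.07 ± 0.73 CPM and from 18.5 ± 5.04 to 4.43 ± 1.13 CPM. Lep, which encodes the fat hormone leptin, fell from 21.1 ± 5.41 to 4.47 ± 2.24 CPM. Tnc, a matrix protein of repairing tissue, rose from 67.9 ± 15.1 to 228 ± 129 CPM, and Selp, which lets leukocytes roll on vessels, from 3.48 ± 1.38 to 9.65 ± 7.21 CPM. Il1f9, which encodes IL-36 gamma, rose from 38.6 ± 14.0 to 264 ± 57.7 CPM, and Saa1, an acute phase protein gene with near-identical relatives, from 0.39 ± 0.16 to 52.7 ± 10.2 CPM.

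Muscle, cartilage, adipocyte and nerve or pigment cell lists fell together after IL-23. Under 3 other scalings the highest median of these 4 lists was -1.19, so the falls do not hinge on the choice among these scalings. They moved genes by a median of 0.033 (RLE), -0.087 (upper-quartile) and -0.21 (plain library size) in log2. These moves are too small to undo such falls, so a larger scaling error was not tested. For an equal dilution of all non-epidermal tissue by RNA of other cells, the changes of 6 lists were compared, which differed by up to 1.504 in log2. Of 15 pairs, 8 were apart by over 0.5 with an adjusted p below 0.05 in an exact permutation test. All 8 included the fibroblast and matrix list or the endothelium list. Both hold genes that rose after IL-23, such as Timp1 and Icam1, and both stood highest in IL-23 intraperitoneal library 28 among the IL-23 libraries. The medians of both lists, given above, also fell less than those of the 4 lists. An equal dilution as the only cause of all 6 changes is thus argued against. Genes that rise lift a list's mean under an equal dilution too, so this test cannot exclude such a dilution beside those rises, which stays open. For an equal dilution of those 4 tissues alone, the largest difference among them was 0.47 and 0 of 6 pairs met both criteria. However, muscle and Schwann cell and melanocyte differed by 0.41 (exact permutation, adjusted p = 0.0343). An exactly equal dilution as the only cause is thus argued against for that pair, while dilution as a part of the cause stays a hypothesis. The mast cell list, whose median fell by a similar amount, was not among the lists compared. A loss or lower activity of these cells under IL-23 stays open and was not tested.

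The clock list fell after IL-23. A later or earlier clock phase at harvest as the only cause is argued against by Arntl and Npas2, which peak opposite to Dbp, Tef, Hlf and Nr1d1. Both fell past the threshold instead of rising, as did at least 3 of those output genes. The higher of the log2 fold changes of Arntl and Npas2 was -0.27 (Arntl, adjusted p = 0.0421), a call near the threshold that was not examined under other scalings. Arntl thus fell less than the list's median, so a phase change on top of a shared fall of clock genes stays open. The list's highest median under 3 other scalings was -0.88, so its fall does not hinge on the choice among these scalings. They moved genes by too little to undo such a fall, so a larger scaling error was not tested. A changed mix of cells, or a lower amplitude under IL-23, stays open and was not tested.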
